A study of Mus musculus with 5 samples.

How the data were processed

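RNA from 5 mouse cell lines was measured on Agilent whole-genome arrays with 1 colour, with 0.25 µg of RNA per sample per the labels' protocols. The deposited values are spot intensities. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background from each intensity, removed spatial and multiplicative trends, and put surrogates in place of values near the background. No normalization between arrays is recorded in the files. The values of the deposited series matrix equalled the processed intensity on 100% of the spots of each array. They are thus linear and not centred, and their column medians ran from 41.5 to 69.3. Each array had 45018 spots, of which 43379 were not controls.

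From the processed intensity, log2 was taken and the 75th percentile of the array subtracted (590.3 to 1074 in signal units). Control spots and outlier-flagged spots were left out, and spots of 1 probe were averaged. Of 41174 probes 41149 had a value on all arrays. Through unversioned RefSeq accessions of assembly GRCm38.p6, 22940 probes were named, 6658 more by a symbol of the file found there, and 11551 kept the file's own name, which can be old. Probes were tested when well above background on every array of at least 1 group, and each gene was represented by its probe with the highest mean, giving 19308 genes. A gene not well above background on any array of a group has only a bound there: its fold is written "at least", as the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

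Groups were taken from the labelled cell type. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 5 arrays with 3 groups and 2 residual degrees of freedom, with Benjamini-Hochberg adjustment. The median SD of a gene was 0.374 in the HPC pair and 0.105 in the iHPC pair, and the single NPC array was assumed to vary like them. An exact permutation test of 2 arrays against 2 could not go below p = 0.333. Gene lists (24 tested, of lineages, processes and other cell types) were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons. List medians and camera used all values as they stand, also those not well above background. Where members are dim in a group, a list median can therefore overstate the difference. No list call held with an estimated correlation, but that test rests on 2 residual degrees of freedom. It lost calls even where the estimate was below 0 (hepatoblast genes -0.0447, interferon-stimulated genes -0.03), so it cannot decide. For Hox genes (0.7913) and plasma protein genes (0.4644) the estimate exceeded the preset, so their camera p-values may be too low. The same holds for mesenchymal (0.3764), hepatocyte metabolic (0.3357) and cell cycle genes (0.1791). It also holds, with smaller estimates, for liver-enriched transcription factors (0.16), neuronal genes (0.0692) and epithelial genes (0.0437). iHPC 9F and 10F were compared without a test, with list medians set against 10000 random lists. The lists, main tests, alternatives and rule for named genes were fixed before the data were examined, except for 1 alternative, the fit on only the groups compared, and the tests of other explanations for unusual patterns, most of which were added later. The rule took, per comparison, the 6 highest and 6 lowest called genes measured in both groups, the 6 largest bounds in each direction, Afp, Alb, Sox2, Pax6 and Nes, and up to 4 members of each list; the text gives part of these, and the others are not reported here. Foxa2 and Cebpa against NPC, Apob, Hhex and Cd24a against HPC, and Fetub and Plg between HPC and NPC were named after their values were seen, to complete small counts.

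The arrays were scanned on 3 days: HPC replicate 1 on the first, HPC replicate 2 on the second, and iHPC and NPC on the third, with iHPC 10F and NPC on 1 slide. On simulated data for 19308 genes with 50 changed at each fold size, the fit for iHPC against NPC recovered 2% of 4-fold, 52% of 16-fold and 96% of 256-fold changes, with 4 false calls. A simulated position of 50% came out as 53.7%. These simulations gave all arrays the same spread for a gene, as the fit assumes. They therefore do not show how the fit errs where groups differ in spread, as the HPC and iHPC pairs did. The alternatives were other normalizations, background corrections, filters, summaries per gene, models, blocks and left-out arrays. Embryonic stem cell arrays and a second neural line of the study were not used here. Figures were drawn with matplotlib 3.10.9.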

Results

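The series holds 5 one-colour microarrays of mouse cell lines, each hybridised with the RNA of 1 culture. The 2 hepatic progenitor cell (HPC) arrays come from the lines HB1 (replicate 1) and HNG2 (replicate 2), which were derived from fetal liver in mice of different strains. The 2 induced hepatic progenitor cell (iHPC) arrays come from a neural progenitor cell (NPC) line infected with retroviruses for 9 transcription factors (iHPC 9F, replicate 1) or 10 (iHPC 10F, replicate 2). The single NPC array is that parental line. The iHPC were placed in the drug G418 3 weeks after infection and kept in it for 1 week. The resistance cassette of the line sits in Afp, which encodes the fetal serum protein alpha-fetoprotein, so Afp transcription was itself selected. Between 58.9% and 65.6% of the non-control spots were well above background on each array, and none was saturated. With 2, 2 and 1 arrays per group, precision is limited by the number of arrays. No label says that the arrays of a group are repeat cultures of 1 condition, so the p-values measure the spread between HB1 and HNG2 and between iHPC 9F and 10F. Levels are log2 signals relative to the 75th percentile of their array, and errors after ± are the SD of 2 arrays. The NPC values have no replicate.

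The first comparison asked how the induced cells differed from the neural line they were made from. The 6 largest bounds for genes higher in iHPC were all of secreted liver proteins. Fgb, a fibrinogen chain, was at 8.14 ± 0.10 in iHPC (n = 2) and not well above background in NPC, at least 13660-fold higher (limma adjusted p = 0.03). Apoa1, the main apolipoprotein of high-density lipoprotein, was at least 5404-fold higher, Ahsg, a fetal plasma glycoprotein, at least 3783-fold, and Hp, the haemoglobin-binding protein haptoglobin, at least 3218-fold. Afp was at least 4721-fold higher (6.61 ± 0.30, n = 2; adjusted p = 0.0336), and Alb, serum albumin, at least 588-fold higher (3.61 ± 0.53, n = 2; adjusted p = 0.0394). Serpina1d was at least 5281-fold higher, but it belongs to a family of near-identical genes and its probe may not separate them. Of the 44 measured plasma protein genes, 25 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 difference of 6.96 (camera adjusted p = 1.58e-19). Members such as Fgb and Apoa1 were not well above background in NPC, so the size of this median may be overstated.

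Epithelial genes rose as a group. Of the 31 measured, 17 rose and 0 fell (22 and 0 adjusted over the list alone; median log2 difference 3.68, camera adjusted p = 1.81e-12). The keratins Krt19 and Krt8, intermediate filament proteins of simple epithelia, were at least 3198-fold and at least 1970-fold higher, and the adhesion protein Cdh1 rose by 5.85 ± 0.65 (SE) on the log2 scale (adjusted p = 0.0363). Of the 22 hepatoblast genes 9 rose and 0 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00264), and of the 29 metabolic genes of mature hepatocytes 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0054), among them Cps1, the first enzyme of the urea cycle, at least 40.3-fold. Among probes well above background on all arrays, the adjusted p was 0.203 for the hepatoblast genes and 0.689 for the metabolic genes, so both calls were lost. Of the 27 liver-enriched transcription factors 7 rose and 2 fell (8 and 4 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.0545), but it passed under 4 of 12 alternatives, namely no filter on dim probes (adjusted p = 0.0136), iHPC arrays as separate groups (0.0135) and without iHPC replicate 1 (0.0108) or replicate 2 (0.0122), and it did not pass with scan day as a block (0.0942) or with fry (0.0932). The bile acid receptor gene Nr1h4 was at least 226-fold higher. Hnf4a was called higher (adjusted p = 0.0264), with a signal in NPC not well above background on the probe used. The 2 that fell were Foxa2, by 3.13 on the log2 scale, and Cebpa, by 2.04. Whether these probes also detect the retroviral transcripts is not known from the sources used here.

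Several matrix genes that were high on the NPC array fell. The gene Mfap4 was at least 1018-fold lower and Fbln5, which organises elastic fibres, at least 474-fold lower. Col1a2, a chain of type I collagen, fell by 7.60 on the log2 scale (SE 1.01, adjusted p = 0.047). Of the 34 mesenchymal genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 1.82e-06), and of the 22 Hox genes 5 fell and 0 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.000202). Sox2, a factor of neural stem cells, fell by 4.86 on the log2 scale (adjusted p = 0.0338), and Pax6 fell by 1.96 (adjusted p = 0.0439). Nes, which encodes the filament protein nestin, was at 2.76 ± 0.14 in iHPC (n = 2) and 1.18 in NPC (adjusted p = 0.238). Of 27 neural progenitor genes 2 fell and 0 rose (4 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0545), but it passed under 5 of 12 alternatives, namely quantile normalization (adjusted p = 0.0494), median centring (0.045), no filter on dim probes (0.0125), iHPC arrays as separate groups (0.0481) and without iHPC replicate 2 (0.0399), and it did not pass with scan day as a block (0.094) or with fry (0.141). Of 30 cell cycle genes 1 rose, Rrm2, a subunit of ribonucleotide reductase (0 adjusted over the list alone), while the list shifted by a median of 0.60 (camera adjusted p = 6.66e-05). For each list called in this comparison, the adjusted p was 0.692 with an estimated correlation, a test that cannot decide on 2 residual degrees of freedom. With fry the calls were lost for Hox genes (adjusted p = 0.141), mesenchymal genes (0.0932), hepatocyte metabolic genes (0.0932) and cell cycle genes (0.0552).

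Over all 19308 genes tested, limma called 1090 at an adjusted p under 0.05, 540 higher in iHPC and 550 lower. The iHPC and NPC arrays were scanned on 1 day, and iHPC 10F shared its slide with NPC. With scan day as a block limma called 6754. The count depends on which pair gives the spread: it was 6754 without HPC replicate 1 or without HPC replicate 2, and 0 without iHPC replicate 1 or without iHPC replicate 2 (2125 and 2122 genes at an unadjusted p under 0.05), where the lone iHPC array was assumed to vary like the HPC pair.

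The second comparison set the induced cells against hepatic progenitors from fetal liver. Rhox5, a homeobox gene of the X chromosome, was 10.66 ± 0.25 (SE) higher in iHPC on the log2 scale (limma adjusted p = 0.0157), at 7.95 ± 0.17 (n = 2) against -2.71 ± 0.28 in HPC (n = 2) and 7.12 in NPC. The steroid dehydrogenase genes Hsd3b4 and Hsd3b5 also rose, Hsd3b5 at least 985-fold, and both belong to a family of similar genes. Zic1, a zinc finger factor of neural tissue, was at least 262-fold higher, at 1.73 in iHPC and 3.70 in NPC. Of the 44 plasma protein genes 12 rose and 1, Apob, fell by 4.90 on the log2 scale (20 rose and 3 fell adjusted over the list alone; median log2 difference of the list 2.10, camera adjusted p = 3.5e-05). The HPC lines lay apart: the list's median over NPC was 5.04 in replicate 1 and 3.12 in replicate 2, against 6.53 in 9F and 7.22 in 10F. Ahsg rose by 6.53 ± 0.19 (SE). Afp (difference 2.13, adjusted p = 0.314) and Alb (0.38, adjusted p = 0.847) did not pass. In HPC replicates 1 and 2, Alb was at 4.61 and 1.84, on either side of its iHPC mean of 3.61. Afp was at 5.98 and 2.98 there, against 6.61 in iHPC. Of the hepatocyte metabolic genes 4 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0282), a call lost without HPC replicate 2 (adjusted p = 0.248), without the filter on dim probes (0.124) and among probes well above background on all arrays (0.0549).

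Of the 22 Hox genes 14 rose and 0 fell against HPC (16 and 0 adjusted over the list alone; median log2 difference 3.56, camera adjusted p = 6.35e-12). Hoxa11 was at least 35.6-fold higher than in HPC, where it was not well above background. It was at -8.04 and -8.57 in HPC replicates 1 and 2, under their lowest signals well above background (-5.99 and -6.62). The list median takes such values as they stand, so its size may be overstated. Of the 25 interferon-stimulated genes 9 rose and 0 fell (17 and 0 adjusted over the list alone, median 2.68, camera adjusted p = 1.44e-09). Ifit3 was 6.68 ± 0.35 (SE) higher on the log2 scale and Oas2 at least 52.5-fold higher. Of the 34 mesenchymal genes 1, the collagen gene Col5a2, rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00264), a call lost without HPC replicate 1 (adjusted p = 0.0702) and among probes well above background on all arrays (0.36).

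Of the 27 liver-enriched transcription factors 9 fell and 0 rose (13 and 1 adjusted over the list alone; median log2 difference -1.66, camera adjusted p = 1.24e-05). Gata6 fell by 6.47 on the log2 scale, Foxa2 by 4.88 and Onecut1 by 4.42. Foxa3 was at least 13.3-fold lower. Of the 18 cyclin-dependent kinase inhibitor and p53 target genes 4 fell and 0 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00374), namely Ccng1, Cdkn1a, Mdm2 and Cdkn1c, and the list's call was lost without HPC replicate 1 (adjusted p = 0.0594). Ccng1 was at 1.18 in iHPC and 1.15 in NPC, Mdm2 at 0.91 and 0.79, and Cdkn1a at 0.18 and -0.89. Cdkn1c was at -7.40 and -3.88. Against NPC the list did not pass (camera adjusted p = 0.618), and HPC were the high group. Of the 22 hepatoblast genes 5 fell (Onecut1, Tbx3, Krt8, Hhex and Cd24a) and 2 rose (Spp1 and Gpc3), with a camera adjusted p of 0.0437; 9 fell and 3 rose adjusted over the list alone. This list did not pass without HPC replicate 1 (adjusted p = 0.0594), without HPC replicate 2 (0.136), with quantile normalization (0.0812), median centring (0.0844) or normexp (0.0689), or among probes well above background on all arrays (0.0737). Hprt, which encodes a purine salvage enzyme, fell by 6.46 on the log2 scale, and the homeobox gene Cdx2 by 5.09. Hprt was at -0.22 in iHPC and -1.33 in NPC. For each list called here the adjusted p was 0.692 with an estimated correlation, which again cannot decide on 2 residual degrees of freedom. With fry the calls were lost for plasma protein genes (adjusted p = 0.0932), hepatocyte metabolic genes (0.142) and mesenchymal genes (0.215).

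In all, limma called 1048 genes between iHPC and HPC, 685 higher and 363 lower in iHPC. The split was 721 and 559 with quantile normalization and 945 and 684 with normexp. No HPC array shared a scan day or slide with an iHPC array, so the day and the cell type cannot be told apart in this comparison. The count was 6987 without HPC replicate 1, 6967 without HPC replicate 2 and 0 without iHPC replicate 1 or without iHPC replicate 2 (1903 and 1936 genes at an unadjusted p under 0.05).

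The third comparison gives the difference between the natural cell types. The keratins Krt8 and Krt7 were at least 12230-fold and at least 9114-fold higher in HPC than in NPC, and Ambp, which encodes a precursor of plasma proteins, at least 2469-fold. Afp was at least 1075-fold higher and Alb at least 451-fold. The last 3 bounds rest on means of HPC lines that lay apart, at 7.36 and 3.99 for Ambp, 5.98 and 2.98 for Afp and 4.61 and 1.84 for Alb in replicates 1 and 2. Zic1 was at least 1029-fold lower in HPC, Hoxa11 at least 520-fold and Sox2 at least 144-fold. Of 31 epithelial genes 16 rose and 0 fell (camera adjusted p = 6.86e-09), of 44 plasma protein genes 18 rose and 2, Fetub and Plg, fell (2.37e-07), and of 27 liver-enriched transcription factors 9 rose and 0 fell (2.18e-05). Of 22 Hox genes 16 fell (5.74e-11), of 34 mesenchymal genes 11 fell (2.37e-07), and of 25 interferon-stimulated genes 10 fell (2.18e-05), with 0 rising in each. Adjusted over the list alone, 21 epithelial genes rose and 1 fell, 27 plasma protein genes rose and 4 fell, 13 transcription factors rose and 2 fell, 17 Hox genes fell and 0 rose, 17 mesenchymal genes fell and 1 rose, and 11 interferon-stimulated genes fell and 0 rose. Hepatoblast (0.00453), cell cycle (0.00426) and p53 target genes (0.0178) shifted up and neuronal genes (0.00435) down. For each of these lists the adjusted p was 0.692 with an estimated correlation, which again cannot decide on 2 residual degrees of freedom. With fry the calls were lost for plasma protein genes (adjusted p = 0.065), mesenchymal genes (0.0503), cell cycle genes (0.065) and neuronal genes (0.0569). The call was lost without HPC replicate 2 for the hepatoblast genes (adjusted p = 0.0845; 0.0934 among probes well above background on all arrays), without HPC replicate 1 for the p53 target genes (adjusted p = 0.0707), and with quantile normalization for the cell cycle genes (adjusted p = 0.0503). Limma called 3024 genes, 1290 higher and 1734 lower in HPC. This split depends on the scaling and filter: it was 1586 and 1575 with median centring, and 1198 and 1147 among probes well above background on all arrays. The count was 9545 without HPC replicate 1, 9762 without HPC replicate 2, and 0 without iHPC replicate 1 or without iHPC replicate 2 (3889 genes at an unadjusted p under 0.05), which leaves the HPC pair alone to give the spread. No HPC array shared a scan day or slide with NPC, so any part of these differences that goes with the day cannot be told apart from the cell type. Krt8 was at 7.94 and 8.03 on the HPC arrays, of 2 different days, and at 5.48 and 5.22 on the iHPC arrays, scanned on the day on which NPC was not well above background.

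**Figure D1:**
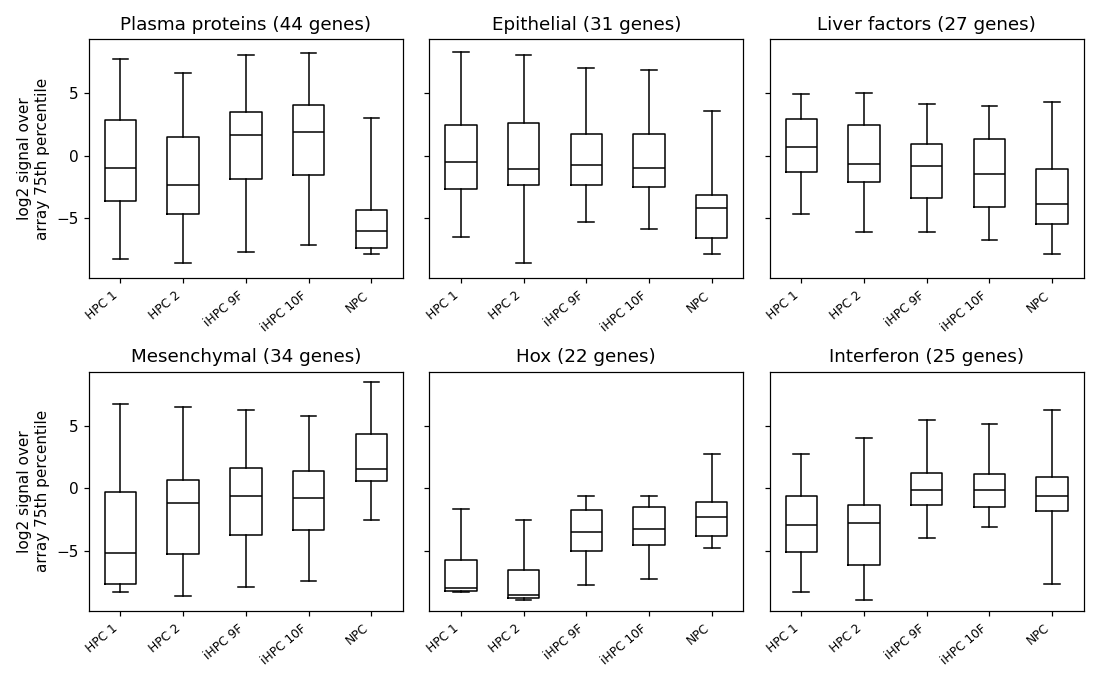
Levels of the measured genes of 6 gene lists on each array, as log2 signal over the array's 75th percentile; boxes span the quartiles, the line is the median and whiskers reach the lowest and highest gene. The plasma protein boxes of both iHPC arrays lie above that of NPC (median difference 6.96), and the Hox boxes of iHPC lie above those of HPC (median difference 3.56). Values not well above background are drawn as they stand, so both medians may overstate the differences.

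Of the 540 genes higher in iHPC than in NPC, 358 were also called higher in HPC than in NPC, and of the 550 lower genes 496 were also called lower in HPC. Independent lists of these sizes would share 36.1 and 49.4 genes. Both comparisons use the same NPC array. In 30 simulations with iHPC left unchanged the overlap was 0, which sets no baseline, since the fit called 0 genes on simulated unchanged data. Part of the excess may come from the shared array, which cannot be split. The covariance of both sets of log2 differences was 2.63 across genes, against 0.271 simulated from the shared array alone. Their correlation was 0.748 against 0.665 simulated in the same way, with no change in any group. Called in opposite directions were 14 genes, higher in iHPC and lower in HPC.

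Unsupervised clustering is the analysis that the series is named for. Average-linkage clustering on Pearson correlation across the 19308 genes joined iHPC 9F with 10F first (r = 0.992), then both HPC lines (r = 0.943), then these pairs with each other, and NPC last. Correlations of iHPC with HPC lay between 0.899 and 0.914 and those with NPC at 0.873 and 0.876. These correlations are across genes, which are not independent replicates. Genes differing at least 4-fold between NPC and 1 HPC line were chosen, and their differences from NPC were signed by that line's direction. Position was the median signed difference of an iHPC array divided by that of the other HPC line, averaged over both choices. It was 63.6% for iHPC 9F and 62.9% for iHPC 10F, with SDs of 4.71 and 3.79 percentage points between both choices. The medians can come from different genes, so the position places no single gene. Simulated data without any change in iHPC gave 3.59%.

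**Figure D2:**
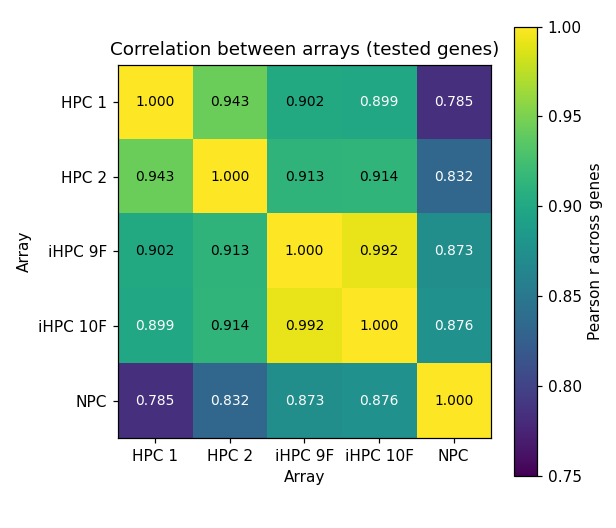
Pearson correlation between each pair of arrays across the 19308 tested genes; both axes list the arrays and the colour gives r. The pair iHPC 9F and 10F has the highest value off the diagonal, 0.992, and HPC replicate 1 with NPC the lowest, 0.785.

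The last comparison asked whether 10 factors rather than 9 went with a different profile. Each condition has 1 array, so the differences have no replicate check. The iHPC 9F and 10F arrays were scanned on 1 day but on different slides, so slide and number of factors cannot be told apart. They also differed in detection, with 62.8% of probes well above background in 9F and 58.65% in 10F. Of 16515 genes measured on both arrays, 42 differed at least 4-fold, 14 higher in 9F and 28 higher in 10F. The count was much lower with normexp and among probes well above background on all arrays. Between both HPC lines 983 of 17140 genes did. In 10F, Iapp, which encodes the islet hormone amylin, was 26.9-fold higher, the opioid precursor gene Penk 16.6-fold and the matrix protease gene Mmp7 9.20-fold. Penk was at 4.06 in NPC, 2.49 in 10F and -1.56 in 9F, so it lay below the parental level in both. Iapp and Mmp7 were at -3.89 and -6.47 in NPC. The sterol acyltransferase gene Soat2 was at least 11.2-fold higher in 10F. Vps13a was 59.9-fold higher in 9F on 1 probe, whereas 3 other probes of the gene differed by a median of 0.06 on the log2 scale. The proton-linked transporter gene Slc16a8 was 5.52-fold higher in 9F. The median plasma protein gene was lower in 9F than in 10F by a log2 difference of -0.37, at percentile 0 among 10000 random lists of matched size and level. Such percentiles also arose between the HPC lines, where this list was at 1.22 and percentile 100 for HB1 minus HNG2. There the mesenchymal and TGF-beta response lists were at percentile 0 and the cholesterol and hepatocyte metabolic lists at 100. The random lists hold unrelated genes, so the percentile cannot tie the difference to the added factor.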

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

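The Vps13a test was fixed before its result was seen; the other tests in this part were chosen after the results they address were seen. No gene list had medians at least 2-fold apart from NPC in opposite directions on the 2 arrays of a pair. The 3 patterns below were weighed.

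Transcripts of the NPC line were present in iHPC: Hox and interferon-stimulated genes measured in NPC kept a median of 74.9% of their NPC level in iHPC 9F and 84.3% in iHPC 10F. The sets moved apart: over all measured genes of each list the median log2 difference from NPC was -1.17 in 9F and -0.99 in 10F for Hox genes, 5 of which were called lower, and 0.22 and 0.27 for interferon-stimulated genes. The first statistic used against unconverted NPC among the iHPC did not argue against them: the 10th percentile of abundant NPC transcripts lay 0.70 below that median on the log2 scale, where 3 had been set as the bound. That statistic was then judged unfit, because most abundant transcripts are shared by all these cells and their percentile does not limit a share of NPC. A second statistic, chosen after the first had failed, counted 7 abundant NPC transcripts under 1% of their NPC level on both iHPC arrays, such as Col1a2 (0.492% and 0.538%), 5 of them well above background on both iHPC arrays and 2 dim there with only an upper limit, which argues against unconverted NPC with the profile of the NPC array; cells that had lost these transcripts stay open. The scan day of the HPC arrays cannot be told apart from the cell type. All measured Hox and interferon-stimulated genes differed by a median of 0.58 between both HPC arrays. Several, such as Hoxa11 (-8.04 and -8.57) and Oas2 (-8.08 and -8.60), were not well above background on either, so 0.58 does not measure an effect of the day. Transcripts retained from the parental line remain a hypothesis.

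Mesenchymal genes were higher (median HB1 minus HNG2 log2 difference -2.28) and plasma protein genes lower (1.22) in HPC replicate 2 than in replicate 1. Hepatocyte metabolic (1.505) and cholesterol genes (1.34) were lower there too, and TGF-beta response genes higher (-0.96). Mesenchymal cells among the HNG2 cells would lower epithelial and plasma protein genes alike. These medians were 0.80 apart (95% interval over resampled genes 0.23 to 1.77). The interval lies above 0 but spans the bound of 1 set for the test, so mixing stays open. Resampling treats the genes of a list as independent and holds no variation between arrays, so the interval may be too narrow. The hepatoblast median was -0.01, with Krt8 at -0.09 and Krt19 at 0.01, but the epithelial median was 0.42. Cdh1 was at 4.57 in replicate 1 and 3.28 in replicate 2. Mixing on the scale of the plasma protein change would lower the keratins too. A small share of mesenchymal cells would barely move them, so they do not decide. These genes were picked after they were seen. Scan day and slide differ between these arrays, so they and the lines, which are of different strains, cannot be told apart.

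Vps13a was 59.9-fold higher in iHPC 9F on 1 probe. The 3 other probes well above background on both arrays differed by a median of 0.0558 on the log2 scale, so a fault of 1 probe or spot may account for it, and a transcript that holds only the part under that probe was not tested.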

How the results depend on the processing

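The fit restricted to the groups compared was chosen after seeing the data. Counts of called genes depended most on which pair gave the spread. With iHPC arrays as separate groups limma called 0 genes in each comparison (2570, 2665 and 3889 at an unadjusted p under 0.05, in the order of the report). Leaving out 1 array gave 0 to 6754 genes for iHPC against NPC, 0 to 6987 for iHPC against HPC and 0 to 9762 for HPC against NPC. With the compared groups alone the counts were 6754, 1048 and 0, and with scan day as a block 6754 for iHPC against NPC. The HPC pair varied more than the iHPC pair. The 1048 is the main fit again, with both pairs, and each of the other fits keeps 1 pair, which shows the cause. Normexp with quantile normalization gave 1993 and 1629 genes in the first and second comparison, no filter on dim probes 305, 460 and 1643, and probes well above background on all arrays 492 and 617; the cause was not tested. The split into higher and lower genes moved too: 540 and 550 became 831 and 1162 with normexp for iHPC against NPC, 685 and 363 became 721 and 559 with quantile normalization for iHPC against HPC, and 1290 and 1734 became 1586 and 1575 with median centring for HPC against NPC. The 25 list calls became 0 with an estimated correlation, with 2 residual degrees of freedom behind that estimate, and 24 with fry, of which 14 were shared. Over the alternatives with camera at the preset correlation, other than the scan-day block, list calls were gained in 30 and lost in 18 of 855 tests. With scan day as a block, and p adjusted over the 24 lists of that comparison alone rather than over all 3 comparisons, 4 more lists passed for iHPC against NPC and none was lost. Between 9F and 10F, 42 genes became 5 with normexp, 18 on probes above background on all arrays, 304 at 2-fold, and 0 by limma with the HPC spread (87 at an unadjusted p under 0.05). The mean correlation of iHPC with HPC exceeded that with NPC by 0.0323, by 0.0244 with normexp, 0.0092 without the filter, 0.0092 on probes above background on all arrays and 0.395 over the 1000 most variable genes; NPC joined last in each. The mean position of 63.2% became 70.5% with normexp, 57.6% at 2-fold and 54.8% to 63.6% leaving out 1 array, where with an HPC array left out the remaining HPC line both chose the genes and set the scale. No named gene changed direction, which could not happen where an alternative alters the spread alone. Of 1494 values under alternatives that keep all arrays, 1243 kept their side of the threshold and 251 lost the call. The fit with iHPC arrays as separate groups lost every call. Leaving out an iHPC array also lost every call, and leaving out an HPC array kept all calls of the main fit. Call changes in these fits therefore say nothing about single named genes. Series matrix values are the same intensities, with flagged spots kept, so they test little. No random block could be estimated for scan day or slide, and a fixed slide block leaves no residual degrees of freedom. No paired analysis was possible because replicate numbers follow accession order and pair nothing.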

Other observations

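The genes below were chosen after their values were seen. The intestinal genes Cdx2, Cdh17 and Vil1 were well above background on all HPC and iHPC arrays and called higher in iHPC than in NPC. Cdx2, a homeobox factor of the intestine, was at 4.53 ± 0.23 in HPC (n = 2), -0.56 ± 0.38 in iHPC (n = 2) and not well above background in NPC, and the intestinal cadherin gene Cdh17 was at 1.83 ± 0.09, -0.02 ± 0.14 and again not well above background in NPC. Vil1, which encodes the brush border protein villin, was at 4.86 ± 1.44 in HPC, 4.12 ± 0.08 in iHPC and -3.54 in NPC. Fabp2, which encodes an intestinal fatty acid-binding protein, was at 0.39 ± 0.45 in HPC but at -5.12 ± 0.20 in iHPC and -4.74 in NPC. The list of intestinal, pancreatic, lung and gastric genes as a whole, with 5 genes called higher and 2 lower in iHPC than in NPC (7 and 3 adjusted over the list alone), did not pass (camera adjusted p = 0.104). It passed in this comparison with no filter on dim probes (adjusted p = 0.0353), with iHPC arrays as separate groups (0.0481), without HPC replicate 2 (0.0475), without iHPC replicate 1 (0.0268), with scan day as a block (0.0446) and with fry (0.0499), and for HPC against NPC with no filter on dim probes (0.0136), with fry (0.0288) and among probes well above background on all arrays (0.0162). Also without a call in any comparison were the lists of cholangiocyte, cholesterol, endothelial, erythroid, glial, imprinted growth, leukocyte, pluripotency, stellate and mesothelial, TGF-beta response, visceral endoderm and neural progenitor genes, with camera adjusted p from 0.0545 to 0.984. Of these the cholangiocyte, cholesterol, glial, imprinted growth, leukocyte, TGF-beta response and neural progenitor genes passed under at least 1 alternative, with the lowest adjusted p, 1.23e-05, for cholesterol genes in iHPC against HPC without HPC replicate 2. The visceral endoderm genes passed with fry alone (0.0288 for iHPC against HPC).

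On the array labelled NPC the brightest probes of the collagen genes Col3a1 and Col1a1 were at 5.67 and 4.98 and their other probes between -5.46 and 1.22. Of the neural genes, Zic1 was at 3.70, Nes at 1.18, Sox2 at 0.86, Slc1a3 at 0.41, Fabp7 at -4.31 and Sox1 at -4.34. Levels of different probes cannot be set against each other as amounts of transcript. Hprt was at 6.24 in HPC, -0.22 in iHPC and -1.33 in NPC. Foxa2 was at 2.98 in NPC and at -0.15 in iHPC, and Cebpa at 1.46 and -0.58. In HPC replicate 2, Cdkn2a and Cdkn2b were not well above background (-8.75 and -8.65), whereas on the other arrays both were, and Mtap was at 0.64. Ddx3y, on the Y chromosome, was not well above background in HPC replicate 2 on either of its probes, while Eif2s3y was at 1.60 there. Xist was well above background on 2 of its 4 probes in both iHPC arrays and on neither of these in NPC, at -2.02 in 9F, -0.58 in 10F and -5.48 in NPC on the brightest.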
